A study of Homo sapiens with 4 samples.

How the data were processed

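Cells of the human embryonic stem cell line H9, either unedited or null for CDK5RAP3, were captured with 10x Genomics gel beads at days 10 and 25 of differentiation towards hepatocytes. There were 4 libraries, 1 for each line and day, and each sample's group was taken from its labels. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 6.0.2 per the file headers. The submitters' processing notes name Cell Ranger 7.1.0 and the build hg19, and this conflict could not be settled. The deposited counts are not normalized. The matrices held 12240 barcodes for the day 10 control, 7644 for the day 10 null, 16580 for the day 25 control and 11918 for the day 25 null library. The lowest UMI count of a barcode was 1252 in the day 25 control library and 500 in the other libraries, a difference already present in the deposited barcodes. Gene IDs and symbols were used as the files give them. Of the IDs, 34616 were found in GENCODE v29, which supplied chromosomes and coordinates on GRCh38. These are not from the authors' build.

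Cells were kept with at least 1000 UMIs, at least 500 genes and under 20% mitochondrial UMIs. This left out 590, 1241, 330 and 1650 barcodes, in the order given above. The kept cells held 258669826, 275063016, 146844955 and 273080455 UMIs. Mitochondrial genes took 0.975%, 0.750%, 3.92% and 2.81% of UMIs, ribosomal protein genes 21.3%, 22.0%, 23.8% and 31.1%, and the 10 most abundant genes 8.35%, 8.32%, 8.72% and 9.29%.

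UMIs were summed over the kept cells of each library and expressed as CPM, counts scaled by the total UMIs of the library. For each gene the log2 ratio of CPM was taken after 0.5 was added to each sum. Intervals are exact Poisson intervals for a level, Clopper-Pearson intervals on the pair of sums for a ratio and Clopper-Pearson intervals for a share of cells, all at 95% and for counting error only. Genes with at least 20 CPM in the higher library of a pair counted as measured, and those at least 2-fold apart were counted. With 1 library per group no comparison had replicates, none was tested, and no p-value was computed. A fit of line and day together would leave 1 residual degree of freedom, which also holds any difference of the line effect between days, and it was not made. The comparisons were null against control at each day and day 25 against day 10 in each line, 4 in all. Where 1 library had 0 counts, a fold in the text is a lower bound against a floor of 3 counts. The log2 ratios, counts and list medians used the added 0.5.

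The gene lists numbered 19. They cover UFMylation, ER stress and the unfolded protein response, ER-phagy and autophagy, the p53 response and apoptosis, pluripotency, definitive endoderm, hepatoblasts, hepatocyte secreted proteins, hepatocyte metabolism, cholesterol and fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, S phase, G2 and M phase, WNT targets, TGF-beta and EMT, interferon and inflammation, immediate early and heat shock genes, and ribosomal proteins. The median log2 ratio of a list's measured genes was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these libraries only. The range of a median came from 1000 resamples of the list's genes, with seed 1.

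Genes were named by a fixed rule. It takes CDK5RAP3, the 12 highest and 12 lowest ratios among genes with at least 50 CPM in the higher library at each day, the 3 members of each list farthest from 0 with at least 20 CPM, and the 8 highest and 8 lowest ratios of each step between days. XIST, Y-linked, mitochondrial and ribosomal protein genes and genes with clone-based or LINC names were left out of the ranking. The rule takes 77 genes at day 10, 73 at day 25 and 16 for each step. The groups, comparisons, thresholds, gene lists, cell type markers, naming rule and most alternatives were set before the data were examined.

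The cells of each day were clustered on the 2000 most variable genes, 30 principal components and 15 exact nearest neighbours with Leiden clustering at resolution 0.5, with no integration of libraries. Doublets were scored against simulated doublets, 2 per cell, and called doublets were left out of the clustering. The caller marked 1 cell (0.009%) in the day 10 control library, where it has not worked, 100 (1.56%) in the day 10 null library, 2016 (12.4%) in the day 25 control library and 1193 (11.6%) in the day 25 null library. The numbers of cells clustered were 11649, 6303, 14234 and 9075. As a further setting the 10% of cells with the highest doublet scores were left out of each library.

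Clusters were named from fixed markers of 12 classes: pluripotent, definitive endoderm, hepatic, cholangiocyte, intestinal or other foregut epithelium, mesenchymal or stellate, endothelial, blood and macrophage, neural, cardiac or skeletal muscle, mesothelial, and trophoblast or extra-embryonic. A marker counted at 2-fold enrichment and 20 CPM. A cluster needed 3 markers and 20 cells, and stayed unnamed where another class had more markers among its 10 leading genes. The names are shortened here to mesenchymal-like and trophoblast-like. No cluster was named for the cholangiocyte, intestinal, blood, muscle or mesothelial classes, and an endothelial-like cluster held 4 control and 34 null cells at day 25. A cluster was treated as low-depth where the median depth of its cells was under 0.5 of the library's median in each library with at least 20 cells in it. Because many marker genes differed between the libraries, the class shares and the day 25 ratios within hepatic-like cells are given from clusters formed without the 246 genes at day 10 and 493 genes at day 25 that were at least 2-fold apart at 5 CPM or more. This setting was chosen after the data were seen. Other values within classes or clusters, and the shares of cells with a UMI in a class, come from the planned clusters, as do values named as planned. To compare shares of cells with a UMI, cells were thinned to 2000 UMIs without replacement.

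Alternatives were all deposited barcodes, a stricter filter (2000 UMIs and 10% mitochondrial UMIs), called doublets left out or kept, median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, equal weight per cell, the deeper library thinned to the other's total, floors of 5 and 100 CPM, Leiden resolutions of 1.0 and 0.25, 30 neighbours, and thinning to 1000 UMIs. Leaving out low-depth clusters or the highest doublet scores, keeping called doublets, and clustering without hepatic genes or without differing genes were added after the data were seen.

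The calculation of the count ratios was checked on simulated data with 200 changed genes. Both simulated libraries were drawn from 1 shared profile with counting error only, without differences of batch, line or cell mix. The numbers therefore do not measure how often 2 real libraries differ by 2-fold without a cause of interest. For the day 10 comparison (6062 genes) 100 of 100 genes changed 3-fold were recovered, 0 of 100 changed 1.5-fold and 0 of 5832 unchanged genes were called, and 91.5% of the intervals held the known value. For day 25 (5794 genes) the numbers were 100 of 100, 0 of 100, 0 of 5564 and 93.5%. For the control step (6089 genes) they were 100 of 100, 0 of 100, 0 of 5859 and 97.0%, and for the null step (5943 genes) 100 of 100, 0 of 100, 0 of 5713 and 95.5%. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9.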

Results

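Single-cell RNA counts were measured in H9 cells, a line of human embryonic stem cells, taken through differentiation towards hepatocytes. The unedited control line and a line in which CDK5RAP3 had been knocked out were each collected at day 10, which the labels call hepatic endoderm, and at day 25, which they call mature hepatocyte. This gave 4 libraries in 4 groups, 1 library per group. After filtering, the day 10 control library held 11650 cells with 258669826 UMIs and the day 10 null library 6403 cells with 275063016. The day 25 control library held 16250 cells with 146844955 UMIs and the day 25 null library 10268 cells with 273080455. The median cell had 16429 UMIs in the day 10 control library and 41744 in the day 10 null library, and 4974.5 and 20868.5 at day 25. There were no replicates, so no difference was tested, and library, batch and genotype cannot be told apart. Intervals are exact, at the 95% level, and cover counting error only.

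The targeted gene was examined as a check of the labels. CDK5RAP3 (ENSG00000108465) lies on chromosome 17 from 47967810 to 47981774 on the plus strand of GRCh38. It encodes an adaptor of the enzyme complex that attaches the ubiquitin-like protein UFM1 to its targets at the endoplasmic reticulum (ER). Its RNA stood at 18.8 CPM (18.3 to 19.3) in the day 10 control library and 2.10 CPM (1.94 to 2.28) in the day 10 null library, 8.93-fold lower. At day 25 it stood at 32.1 CPM (31.2 to 33.0) in the control library and 4.35 CPM (4.11 to 4.61) in the null library, 7.37-fold lower. The log2 ratios were −3.16 (−3.29 to −3.03) and −2.88 (−2.97 to −2.79). The library sums behind these levels were 4864, 579, 4713 and 1189 UMIs. Counts near the 3' end of a transcript can persist in a null line, so the RNA still counted in the null libraries does not go against their labels.

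**Figure D1:**
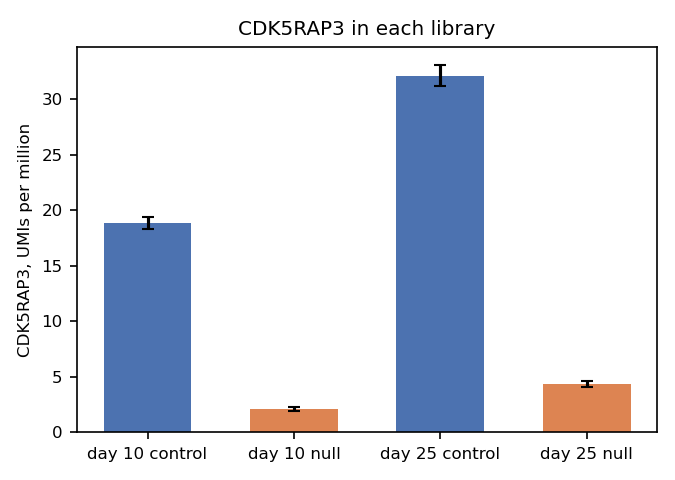
Level of CDK5RAP3 RNA in CPM (vertical axis) in the 4 libraries, with bars for the library values and error bars for exact Poisson 95% intervals. The null libraries stand at 2.10 and 4.35 CPM, below the control libraries at 18.8 and 32.1 CPM.

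The day 10 comparison asks how the null cells differed at the hepatic endoderm stage. The list of hepatocyte secreted proteins had the lowest median log2 ratio, −0.74 over 13 genes, and hepatic genes did not all move alike. TTR, a thyroid hormone carrier secreted by hepatic cells, stood at 99.9 CPM in the null library and 444 CPM in the control library, 4.45-fold lower. HNF4A, a transcription factor of hepatic fate, stood at 29.05 and 81.7 CPM, 2.81-fold lower, and DLK1, a surface protein of hepatoblasts, at 25.4 and 91.7 CPM, 3.62-fold lower. AFP, the fetal albumin homologue, was higher but below the expression floor of the lists (15.2 and 6.43 CPM). The highest ratios among genes with at least 50 CPM in the higher library belonged to the transcription factor HAND1 (6.66-fold higher), the cardiac actin ACTC1 (6.56-fold) and the collagen I chains COL1A1 (84.0 and 17.2 CPM, 4.89-fold) and COL1A2 (55.9 and 12.1 CPM, 4.62-fold). Cells of a mesenchymal-like class were 4.43% of the null library and 0.498% of the control library, and 5.68% and 1.18% in the planned clusters.

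Among 6304 genes measured at day 10, 57 were at least 2-fold higher and 30 at least 2-fold lower in the null library, together 1.38%. The median log2 ratio of all genes was 0.03. With the same floor of 50 CPM, others among the 12 highest were TIMP1, an inhibitor of matrix metalloproteinases (297 and 91.0 CPM, 3.26-fold), the neuropeptide precursor NTS (538 and 170 CPM, 3.17-fold), the major histocompatibility gene HLA-DQB1 (3.62-fold), the prostaglandin-degrading enzyme HPGD (3.47-fold) and the annexin ANXA1 (2.88-fold). Others among the 12 lowest were LRRC75A (5.14-fold), the progenitor surface protein CD34 (2.71-fold), the receptor ERBB4 (2.53-fold), the mitotic kinase NEK2 (2.44-fold), the serine synthesis enzyme PSAT1 (132 and 320 CPM, 2.42-fold), the stress-linked transcription factor ATF5 (2.37-fold) and BTF3, a chaperone of nascent proteins (391 and 897 CPM, 2.29-fold). None of the counting intervals of the named ratios at day 10 included 0. Day 10 planned cluster 5 weighs heavily in these sums, with 92032802 control UMIs. It held 12.2% of control and 0.301% of null cells, and LRRC75A, HNF4A, TTR, DLK1, VTN and ATF5 were among its leading genes. Its control cells had a median depth of 3.61 times the library's, and 24.1% had doublet scores in the top 10%. Without the highest doublet scores 84 of the 87 genes stayed at least 2-fold apart, and 74 with equal weight per cell.

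The hepatic lists had medians below 0 at day 10. Over resampled genes the range left out 0 for hepatocyte secreted proteins (−1.05 to −0.31). It included 0 for hepatoblast (−1.08 to 0.05), hepatocyte metabolism (−1.36 to 0.17) and definitive endoderm genes (−0.42 to 0.40). Of 13 measured hepatocyte secreted proteins, 11 were below 0 and 4 at least 2-fold lower, with a median log2 ratio of −0.74 at percentile 0.0 of 10000 random lists matched on expression. The vitronectin gene VTN (−1.58) and the lipoprotein assembly gene MTTP (−1.18) were among them. Of 12 hepatoblast genes, 3 were at least 2-fold lower and 1 at least 2-fold higher (median −0.24, percentile 0.13). Of 5 hepatocyte metabolism genes, 4 were below 0 (median −0.55, percentile 0.02), with PCK2, a gluconeogenic enzyme of mitochondria, at −1.36. Of 11 definitive endoderm genes, 7 were below 0 (median −0.22, percentile 0.30), and they moved apart: HHEX, a transcription factor of liver budding, stood at −1.77 and MIXL1, a mesendoderm gene, at 0.78. The pluripotency list stood at 0.12 (percentile 89.9, 10 genes), with the stem cell factor POU5F1 at 227 and 129 CPM (0.81). Pluripotent-like cells were 14.8% of the null library and 6.77% of the control library.

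Genes of the ER and of UFM1 attachment were slightly higher at day 10. Of 8 measured UFMylation genes, 7 were above 0 (median 0.32, percentile 99.7), led by DDRGK1 (0.47) and UFL1 (0.41), the partners of CDK5RAP3 in the ligase complex, and UFM1 (0.41). CDK5RAP3 itself was under the expression floor of this list at day 10. Of 24 ER stress and unfolded protein response genes, 20 were above 0 (median 0.26, percentile 100). Under median-of-ratios scaling these counts were 6 and 18, with medians of 0.23 and 0.17. They included the ER chaperone HSPA5 (539 and 336 CPM, 0.68) and SDF2L1 (0.81), while CHAC1, a target of the amino acid response, stood at −1.30. Within the planned clusters this list had medians of 0.36 in definitive endoderm-like cells, 0.26 in pluripotent-like cells and 0.02 in mesenchymal-like cells. These medians do not cover the hepatic-like class (36.7% of control and 3.66% of null cells) or the unnamed clusters (52.4% and 73.1%). The ER-phagy and autophagy list stood at 0.12 (percentile 93.1, 16 genes) with OPTN at 0.33, and the p53 list at 0.22 (percentile 99.2, 12 genes) with CDKN1A, a cell cycle inhibitor, at 0.63.

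Cell cycle genes were lower in the day 10 null library. Of 36 G2 and M phase genes, 34 were below 0 (median −0.30, percentile 0.0), with HMGB2 at −0.88 and the kinase CDK1 at −0.82. Of 21 S phase genes, 17 were below 0 (median −0.09, percentile 1.30), with MCM7 at −0.35. The 3 measured interferon and inflammation genes were below 0 (median −0.43, percentile 0.645), with ISG15 at −0.63. The oxidative phosphorylation list stood at −0.08 (percentile 10.1, 27 genes) with COX6C at −0.40, and the WNT target list at 0.20 (percentile 91.2, 3 genes) with SP5 at −0.52. The remaining lists had medians near 0 whose sign turned under another scaling. These were TGF-beta and EMT (0.03, and −0.07 under median-of-ratios scaling; VIM 1.18), cholesterol and fatty acid synthesis (0.08, and −0.01; ELOVL6 0.34), immediate early and heat shock (0.08, and −0.01; HSPA1B −0.65), ribosomal proteins (0.05, and −0.05; RPS27 0.25) and glycolysis and hypoxia, where the median was −0.00 and 10 of 21 genes were above 0 (SLC2A1 0.60).

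**Figure D2:**
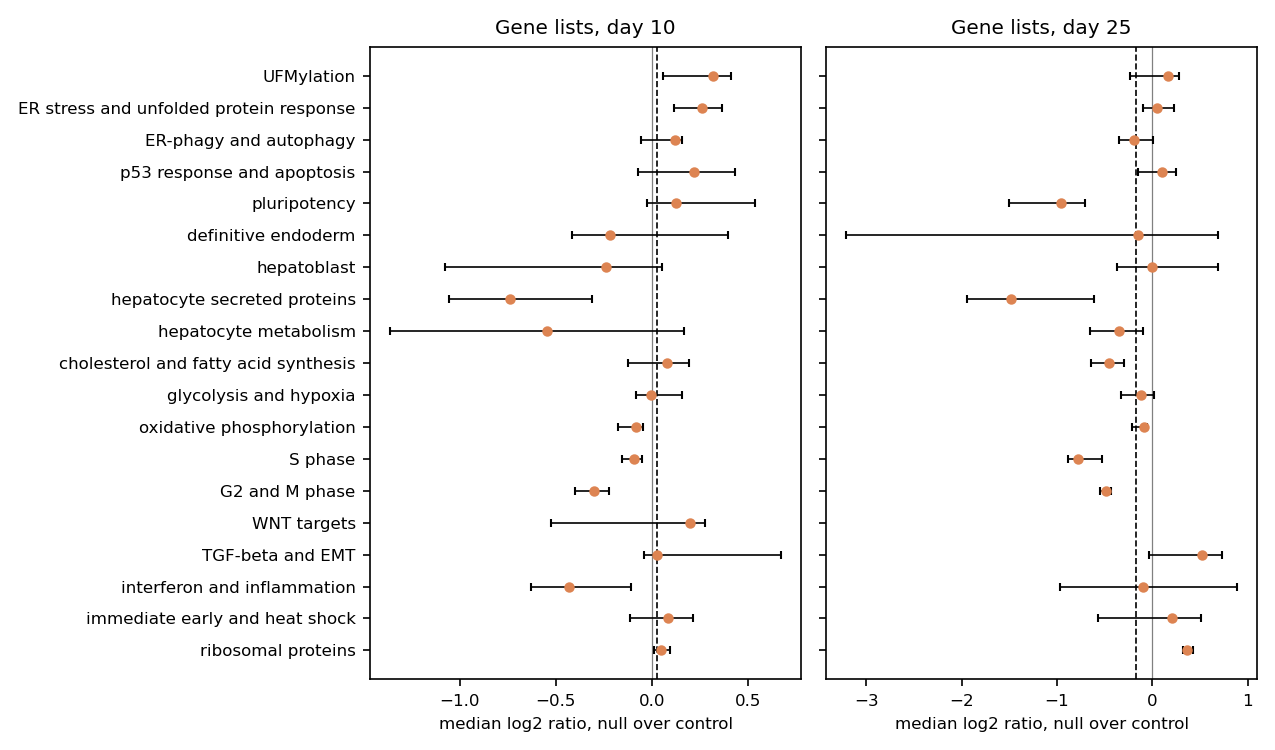
Median log2 ratio, null over control (horizontal axis), of each gene list at day 10 and day 25, with points for medians, error bars for the 95% range over resampled list genes and a dashed line at the median of all genes. Hepatocyte secreted proteins stood at −0.74 and −1.49; medians near 0, such as ribosomal proteins at day 10 and ER stress at day 25, change sign under other settings.

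The day 25 comparison asks how the null cells differed at the hepatocyte stage. The list of hepatocyte secreted proteins had the lowest median log2 ratio, −1.49 over 30 genes. ALB, serum albumin, stood at 104 CPM in the null library and 1337 CPM in the control library, 12.8-fold lower (log2 ratio −3.68, −3.70 to −3.66). The apolipoproteins APOA4 (39.6 and 621 CPM) and APOC3 (90.4 and 754 CPM) were 15.7-fold and 8.34-fold lower, the glycoprotein AHSG (17.3 and 205 CPM) 11.9-fold lower and SERPINA1, alpha-1-antitrypsin (325 and 1882 CPM), 5.78-fold lower. Among the 12 highest ratios of genes with at least 50 CPM in the higher library were COL3A1, a chain of collagen III (1225 and 390 CPM, 3.14-fold), COL6A2 (3.09-fold), the matrix protein POSTN (3.46-fold) and TIMP1 (1248 and 378 CPM, 3.30-fold). Cells of clusters named mesenchymal-like were 36.5% of the null library and 4.64% of the control library, leaving out unnamed clusters with mesenchymal markers.

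Among 6186 genes measured at day 25, 113 were at least 2-fold higher and 87 at least 2-fold lower in the null library, together 3.23%. The median log2 ratio of all genes was −0.18, and −0.04 with median-of-ratios scaling, under which the split was 145 higher and 66 lower. With totals that left out mitochondrial and ribosomal protein genes the split was 142 and 66. At a floor of 50 CPM in the higher library, the highest ratio belonged to S100A6, a calcium-binding protein (246 and 3.77 CPM, 65.2-fold, log2 6.03, 5.91 to 6.15), followed by the potassium channel subunit KCNE4 (6.87-fold), the microfibril protein MFAP4 (4.48-fold) and TNFAIP3, an inhibitor of NF-kappaB signalling (4.34-fold). NR4A1, an early response nuclear receptor, was 3.14-fold higher. The lowest ratio belonged to CRABP1, a retinoic acid binding protein (16.2 and 582 CPM, 35.9-fold). CRABP1 led a neural-like cluster that held 7.42% of the control library and 0.287% of the null library. The acute phase genes SERPINA3 (11.9-fold), HP (8.59-fold) and ORM1 (7.76-fold) and the neuropeptide gene NTS (5.87-fold) were also among the 12 lowest. None of the counting intervals of the named ratios at day 25 included 0.

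**Figure D3:**
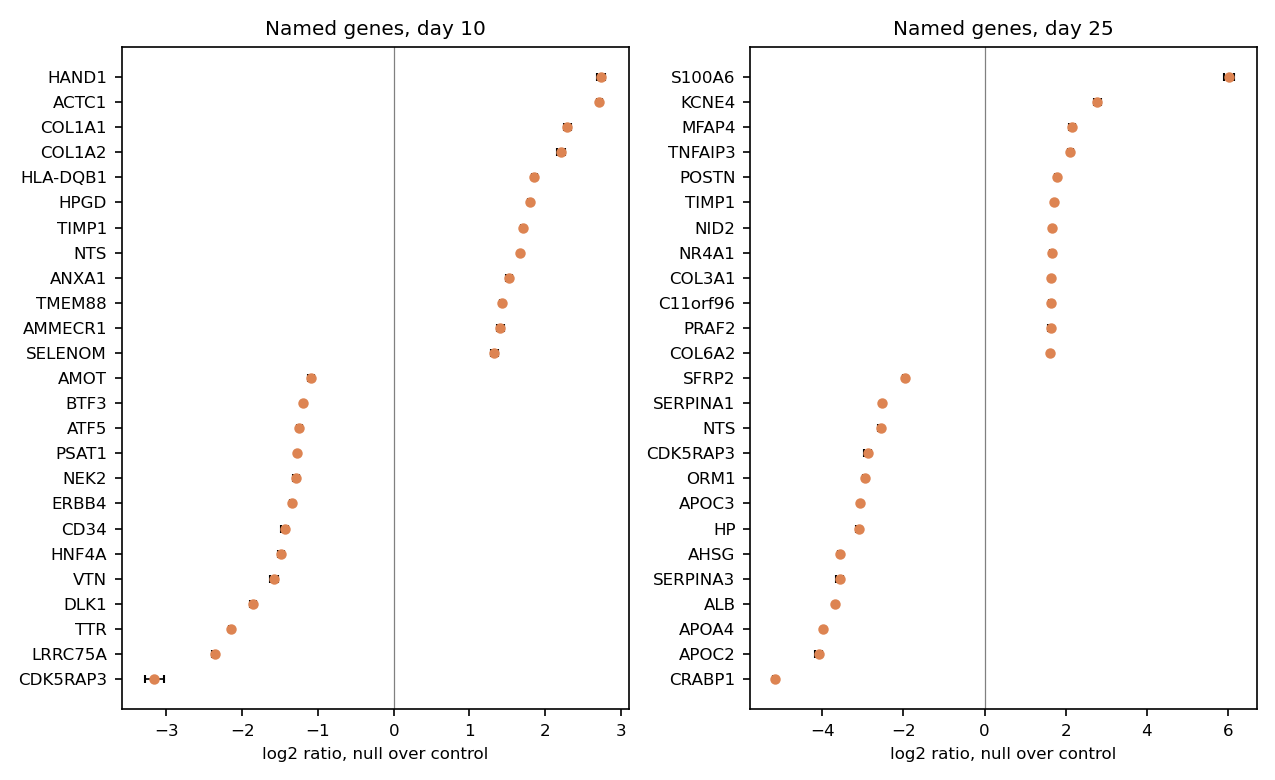
Log2 ratio, null over control (horizontal axis), of CDK5RAP3 and the 12 highest and 12 lowest named genes at day 10 and day 25, with points for ratios of library sums and error bars for counting intervals. HAND1 (2.74) and LRRC75A (−2.36) lie outermost at day 10 apart from CDK5RAP3, and S100A6 (6.03) and CRABP1 (−5.17) at day 25.

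Day 25 list medians are given relative to the median of all genes, while ratios of single genes and counts above or below 0 are not. Of 30 hepatocyte secreted proteins, 28 were below 0 and 16 at least 2-fold lower, and the list stood at −1.31 (−1.49 before subtraction, percentile 0.0). The hepatocyte metabolism list stood at −0.18 (percentile 4.54, 9 genes), with the asialoglycoprotein receptor ASGR1 at −0.78 and the retinal dehydrogenase ALDH1A1 at 0.82. The cholesterol and fatty acid synthesis list stood at −0.28 (percentile 0.01), with 18 of 19 genes below 0, HMGCS1 at −0.83 and FDPS at −0.72. Hepatoblast genes moved apart, 3 at least 2-fold higher and 2 lower (0.17 relative to all genes, percentile 62.0). The imprinted fetal genes IGF2 (299 and 104 CPM, 1.52) and DLK1 (747 and 263 CPM, 1.51) were higher and the trypsin inhibitor SPINK1 was lower (946 and 2582 CPM, −1.45).

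Pluripotency and proliferation genes were lower at day 25 as well. All 10 pluripotency genes were below 0 and 4 at least 2-fold lower (−0.78, percentile 0.0), with SOX2 and L1TD1 at −1.51 each. Pluripotent-like cells were 5.79% of the null library and 7.09% of the control library, and 5.96% and 12.8% outside low-depth clusters. Within pluripotent-like planned cluster 6, POU5F1 stood at 1190 CPM in null and 1135 CPM in control cells. The whole-library pluripotency median was not separated from the difference in class shares. All 20 S phase genes (−0.60, percentile 0.0; MCM4 −1.02) and all 35 G2 and M phase genes (−0.31, percentile 0.0; CENPF −0.87) were below 0. These counts were the same under median-of-ratios scaling. The definitive endoderm list stood at 0.02 (percentile 66.8, 5 genes) with CER1 at −3.22 and MIXL1 at −2.85. The TGF-beta and EMT list stood at 0.70 (percentile 100, 13 genes), with the matrix gene THBS1 at 1.20 and the transcription factor SNAI2 at 1.01. Before subtraction its median was 0.52 (−0.03 to 0.73 over resampled genes), with 9 genes above 0 and 4 below. Mesenchymal-like cells were 36.5% of the null and 4.64% of the control library, and this whole-library median was not separated from that difference. Immediate early and heat shock genes stood at 0.38 (percentile 99.6, 17 genes), with FOSB at 1.35 and HSPH1 at −0.74.

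The UFMylation list stood at 0.34 at day 25 (percentile 98.9, 8 genes including CDK5RAP3), with DDRGK1 at 0.39. Before subtraction its median was 0.17 (−0.23 to 0.28 over resampled genes), with 5 genes above 0 and 3 below. The ER stress list stood at 0.22 (percentile 96.9, 23 genes) with ATF3 (1.17) and PPP1R15A (1.07), both of the integrated stress response, at least 2-fold higher. Its unsubtracted median of 0.04 turned to −0.05 with equal weight per cell. The p53 list stood at 0.28 (percentile 99.4, 14 genes) with BTG2 at 0.75 and the ER-phagy list at −0.02 (percentile 36.6, 16 genes) with MAP1LC3B at −0.52. All 23 ribosomal protein genes were above 0 (0.54, percentile 99.9), with RPS27 at 0.85, and ribosomal protein genes took 31.1% of UMIs in the null library and 23.8% in the control library. The interferon and inflammation list stood at 0.08 (percentile 81.5, 9 genes), with the chemokine CCL2 at 2.41 and the acute phase gene SAA2 at −4.06. The glycolysis (0.06, percentile 47.8, 20 genes; P4HA1 0.76) and oxidative phosphorylation lists (0.08, percentile 49.0, 27 genes; SDHB −0.43) lay near the median of all genes. Before subtraction the medians of the definitive endoderm (−0.15), hepatoblast (−0.01), glycolysis (−0.12), interferon (−0.09) and oxidative phosphorylation lists (−0.09) were below 0, and each turned above 0 under another setting. Of the WNT targets 1 was measured, BAMBI, at 0.23.

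Cells were clustered for each day, and class shares are given from clusters formed without the genes at least 2-fold apart between the libraries. With 1 library per group a cluster mostly of 1 library may be that library, not a type. At day 10 the shares in control and null were 6.77% (6.32 to 7.24) and 14.8% (13.9 to 15.7) for pluripotent-like, 4.05% and 5.76% for definitive endoderm-like and 0.498% (0.378 to 0.643) and 4.43% (3.93 to 4.96) for mesenchymal-like cells. The other 88.7% and 75.0% had no name, and no hepatic-like cluster was named at day 10 in this setting. In the planned clusters, formed with the differing genes, a hepatic-like class held 36.7% (35.8 to 37.5) of control and 3.66% (3.21 to 4.16) of null cells. In the 4 other settings that named it, the shares were 16.5% to 39.0% and 2.24% to 3.90%. Planned cluster 3, unnamed and with AFP among its leading genes, held 1.91% of control and 38.2% of null cells. APOA1 stood at 13297 CPM in its null cells and 13931 CPM in the hepatic-like control cells, but also at 9205 CPM in control cells of unnamed planned cluster 2. TTR (148 and 665 CPM), APOB (251 and 403 CPM), HNF4A (39.4 and 88.2 CPM) and VTN (23.3 and 62.2 CPM) were lower in those null cells, and AFP (21.8 and 5.40 CPM) was higher. Control cells of planned cluster 3 lay between these levels (TTR 252, APOB 266, HNF4A 50.1, VTN 39.6 and AFP 7.22 CPM). Without the differing genes, an unnamed cluster led by TTR held 35.7% of control and 14.3% of null cells. The planned clusters were formed in part by these genes, so the levels cannot tell how much of the gap between the hepatic-like shares comes from clustering. At day 25 the class shares in control and null were 4.64% (4.297 to 4.995) and 36.5% (35.5 to 37.5) for mesenchymal-like cells. They were 7.42% (6.99 to 7.86) and 0.287% (0.187 to 0.420) for neural-like and 6.63% (6.22 to 7.05) and 12.2% (11.5 to 12.9) for trophoblast-like cells. For pluripotent-like cells they were 7.09% and 5.79%, and for definitive endoderm-like cells 2.27% and 1.25%. Of the pair of mesenchymal-like clusters at day 25, the smaller was led by mitotic genes, and 17.9% and 22.9% of cells had no name. Among these, cluster 4, with 8 mesenchymal markers, held 4.26% of control and 9.32% of null cells. Cluster 16, with 9 such markers, held 0.548% and 1.76%. The mesenchymal-like shares leave both out. Low-depth clusters held far more of the control library at day 25 and dilute its shares. Outside them the shares in control and null were 8.39% and 37.6% for mesenchymal-like, 13.4% and 0.295% for neural-like, 11.99% (11.3 to 12.7) and 12.5% (11.8 to 13.2) for trophoblast-like, 12.8% and 5.96% for pluripotent-like and 4.11% and 1.28% for definitive endoderm-like cells.

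The day 25 hepatic-like shares depended on the genes used to cluster, on low-depth clusters and on which clusters were named. Hepatic-like cells were 54.1% (53.3 to 54.9) of the control library and 21.1% (20.3 to 22.0) of the null library. A low-depth cluster, whose median cell had 0.492 of its library's median UMIs, held 44.5% of control cells and 1.22% of null cells. Outside low-depth clusters the hepatic-like shares were 17.3% (16.5 to 18.2; 1361 of 7868 cells) and 20.5% (19.6 to 21.3; 1804 of 8813 cells). The planned clusters gave 23.3% and 0.697%, and Leiden resolution 1.0 gave 25.9% and 4.36%. The planned shares leave out planned cluster 3, which had 9 hepatic markers and held 3.81% of control and 20.8% of null cells. It stayed unnamed because another class had more markers among its 10 leading genes. The gap between the planned shares therefore rests in part on the naming rule. A shallow hepatic-like control cluster lay close to the depth limit in some settings. When every cluster under 0.6 of the median depth was left out, a limit chosen after the data were seen, the shares were 20.8% and 23.1% at Leiden resolution 0.25 and 27.1% and 23.1% without hepatic genes. At that limit the null share stayed far lower in most other settings, with 23.9% and 0.700% in the planned clusters, 16.9% and 0.604% with all barcodes, 18.5% and 0.634% with the stricter filter, 28.0% and 0.680% with doublets kept, 21.1% and 0.768% with 30 neighbours and 26.8% and 4.52% at Leiden resolution 1.0. A further cluster with 12 hepatic markers, led by NPPB and ACTA1, stayed unnamed and held 4.82% and 0.893%.

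**Figure D4:**
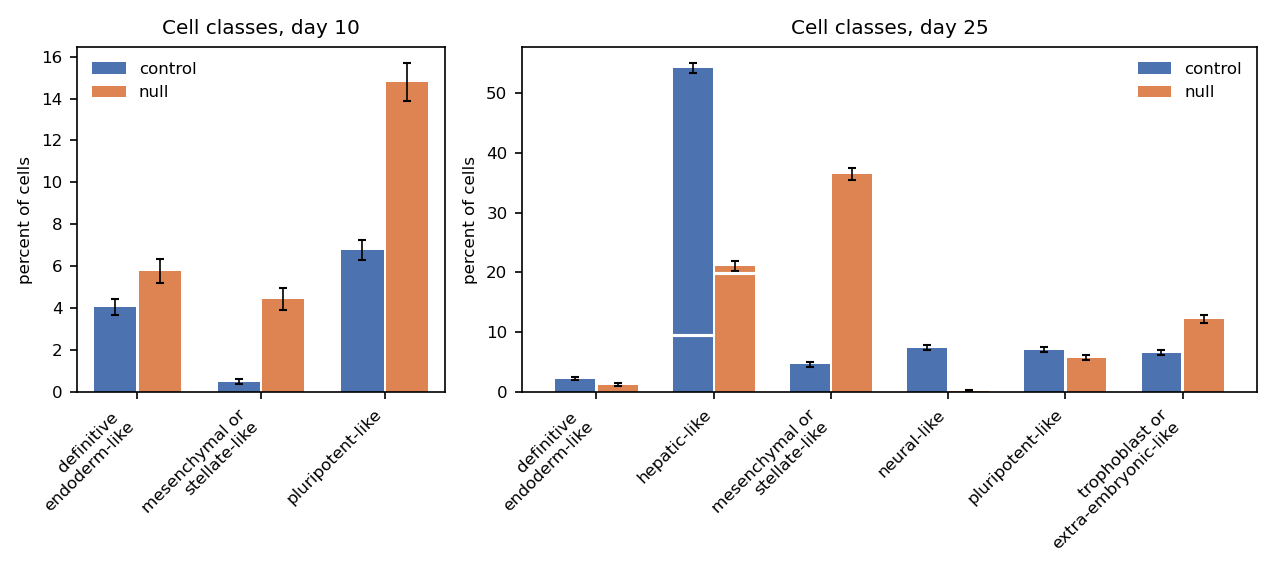
Percent of cells (vertical axis) in each named class at day 10 and day 25 in the control and null libraries, from clusters formed without the differing genes, with exact binomial 95% error bars. Mesenchymal-like cells were 4.64% of control and 36.5% of null cells at day 25; the white lines in the hepatic-like bars mark the part outside low-depth clusters.

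The hepatic-like class outside low-depth clusters at day 25 pools cells that the planned clusters keep apart. Of its cells, 60.6% in control and 2.49% in null lay in planned cluster 5, which was hepatic-like. Planned cluster 3, an unnamed cluster led by AGR2 and with 9 hepatic markers, held 34.2% and 96.6%. Over the pooled class, ALB stood at 290 CPM in null and 4367 CPM in control cells (log2 ratio −3.91, −3.94 to −3.89), APOA4 at 119 and 2064 CPM (−4.12), APOC3 at 281 and 2420 CPM (−3.11) and SERPINA1 at 1025 and 5697 CPM (−2.48). AFP stood at 13865 and 33316 CPM (−1.26), TTR at −1.14, APOA1 at −0.73, HNF4A at −0.38, the fibrinogen chain FGB at −0.16 and MTTP at 0.08. These genes were chosen from the fixed hepatic lists after their values were seen. Of 35 hepatocyte secreted proteins, 22 were at least 2-fold lower, with a median of −1.74 (−2.37 to −0.73 over resampled genes) beside a median of all genes of 0.00. The cells came from cluster 3 (1202 control and 1444 null cells), cluster 13 (94 and 348) and cluster 19 (65 and 12). Where clusters were formed with the differing genes, the hepatic-like class held 1911 control and 62 null cells, without planned cluster 3. Its list median was 0.02, so the comparison within this class depends on the genes used to cluster and on which clusters were named. Within planned cluster 3 the list median was −0.10 (−0.63 to 0.45 over resampled genes, 30 genes), with ALB at 161 CPM in null and 303 CPM in control cells. Within planned cluster 5 it was −0.15 (−0.59 to 0.07, 36 genes), with ALB at 1074 and 3502 CPM. The pooled ratios therefore include the unequal shares of these clusters, which were themselves formed in part by the same genes.

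**Figure D5:**
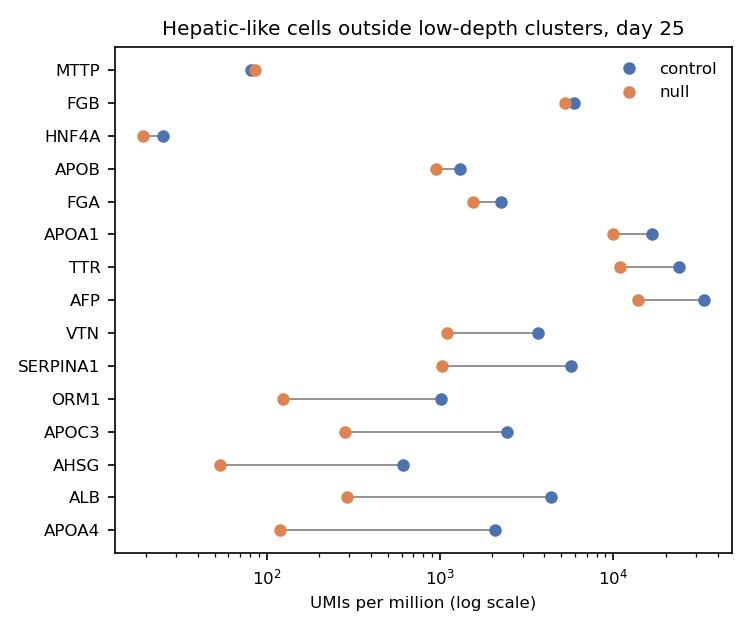
Level in CPM (horizontal log axis) of 15 hepatic genes, chosen after their values were seen, in hepatic-like cells outside low-depth clusters at day 25, with 1 point per library and no error bars. ALB stands at 4367 CPM in control and 290 CPM in null cells, while FGB and MTTP lie close together; the class pools planned clusters held unequally by the libraries.

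Shares of cells with a UMI were compared after each cell was thinned to 2000 UMIs, which left out 2378 control and 322 null cells at day 25. The classes set beside these shares, at both days, are those of the planned clusters. ALB was seen in 42.5% (41.7 to 43.3) of 13872 control cells and 3.72% (3.36 to 4.11) of 9946 null cells, whose median depths were 6522 and 21392.5 UMIs. Unthinned shares were 69.2% and 19.5%. In pluripotent-like cells, which should lack the gene, the thinned shares were 15.5% and 0.491% at median depths of 15194.5 and 31219 UMIs, a measure of free RNA. AFP was seen in 94.2% and 73.0% of all cells (unthinned 99.99% and 99.9%; pluripotent-like 86.8% and 65.6%), TTR in 81.7% and 48.7% (99.1% and 95.2%; 54.5% and 33.4%) and APOA1 in 78.6% and 51.9% (97.7% and 96.4%; 50.4% and 34.9%). POU5F1 was seen in 31.4% and 12.7% (unthinned 45.2% and 28.1%; mesenchymal-like 3.50% and 2.01%, at median depths of 12379 and 17589 UMIs). COL1A1 was seen in 47.5% and 65.9% (70.4% and 93.5%; pluripotent-like 13.8% and 19.4%). MKI67, a proliferation marker with no class here that should lack it, was seen in 14.6% and 8.75% (28.6% and 29.5%).

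At day 10 thinning left out 757 control and 169 null cells, and 10893 and 6234 remained, with median depths of 17367 and 42421 UMIs. TTR was seen in 31.6% of control and 10.1% of null cells (unthinned 65.3% and 42.8%), beside 4.46% and 1.32% in pluripotent-like cells at median depths of 15133.5 and 32844 UMIs. APOA1 was seen in 96.4% and 88.1% (99.9% and 99.9%; pluripotent-like 66.9% and 56.1%). POU5F1 was seen in 11.03% and 18.6% (22.1% and 43.0%; definitive endoderm-like 1.13% and 2.28%). COL1A1 was seen in 2.74% and 6.56% (16.0% and 38.3%), beside 3.38% and 6.20% in pluripotent-like cells, 2.03% and 1.95% in definitive endoderm-like cells and 54.4% and 63.0% in mesenchymal-like cells. MKI67 was seen in 12.4% and 10.4% (40.6% and 39.6%). AFP (1.06% and 1.88%; unthinned 7.65% and 19.6%; pluripotent-like 1.69% and 0.396%) and ALB (0.174% and 0.176%; 1.88% and 3.09%) were seen in few cells.

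From day 10 to day 25, the list of hepatocyte secreted proteins was higher and the definitive endoderm list lower in both lines, with medians given below. In the control line AFP went from 6.43 to 10921 CPM (1699-fold), ALB from 0.939 to 1337 CPM (1421-fold), and SERPINA1 from 0.0387 CPM (10 UMIs) to 1882 CPM. SAA1, an acute phase protein, had 0 counts at day 10 and 96.1 CPM at day 25, at least 8283-fold higher against a floor of 3 counts. In the null line AFP went from 15.2 to 4563 CPM (300.3-fold) and SERPINA1 from 0.0145 CPM (4 UMIs) to 325 CPM. KCNE4 (737-fold), the growth factor AREG (584-fold), CXCL2 (556-fold) and the secretory protein AGR2 (0.204 to 97.2 CPM, 473-fold) were also among the 8 highest of the null line. Among the lowest were CD34 (382-fold), the chemokine receptor CXCR4 (35.0-fold) and the endoderm factor SOX17 (274 to 8.88 CPM, 30.8-fold) in the control line. In the null line these were the mesendoderm factor EOMES (107 to 0.410 CPM, 259-fold), LHX1 (137-fold), CXCR4 (56.9-fold) and NTS (54.3-fold).

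In the control line 643 of 6790 genes were at least 2-fold higher at day 25 and 605 lower, or 512 and 907 under median-of-ratios scaling, which moved the median of all genes from −0.12 to −0.35. In the null line 594 of 6742 genes were higher and 942 lower, with a median of −0.33. Both lines had 420 of the higher genes and 452 of the lower genes in common. Relative to the median of all genes, hepatocyte secreted proteins stood at 5.27 in the control line (31 genes, 24 at least 2-fold higher) and 4.52 in the null line (23 genes, 14 higher). Hepatocyte metabolism stood at 2.23 (11 genes) and 3.06 (10 genes) and definitive endoderm at −2.28 (11 genes) and −2.56 (10 genes). Hepatoblast stood at −0.41 (6 genes at least 2-fold higher and 6 lower) and −0.45 (6 and 5). TGF-beta and EMT stood at 2.90 and 2.22 and cholesterol and fatty acid synthesis at −0.78 and −1.02. The floor was applied in each line, so the medians of the lines can rest on different genes of a list. The pluripotency list stood at 0.80 in the control line and −0.36 in the null line, and the S phase list at −0.19 and −0.76. Differences between the lines in these steps were not tested.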

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

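Of all genes measured on both days, 4 lay at least 2-fold apart between null and control in opposite directions on the 2 days, and DLK1 and NTS are those the fixed rule names. The difference between days was not tested. DLK1, an imprinted surface protein, had a log2 ratio of −1.85 at day 10 and 1.51 at day 25, a difference of 3.36. NTS, which encodes neurotensin, had 1.67 at day 10 and −2.55 at day 25, a difference of −4.22. At day 25 DLK1 was among the leading genes of a mesenchymal-like cluster and NTS led a definitive endoderm-like cluster.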

How the results depend on the processing

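No paired analysis was possible because each of the 4 comparisons sets 1 library against 1 other and no result comes from a test. A fit of line and day together over all 4 libraries is another comparison, and it was not made. Of the genes at least 2-fold apart, 74 to 87 of 87 at day 10 and 179 to 199 of 200 at day 25 were still so under the alternatives with the same floor, and 0 had the other sign. No named gene's ratio changed sign (693 values at day 10, 657 at day 25), though 190 and 311 of these moved beyond counting error. Of the list medians, 187 of 192 values at day 10 and 170 of 182 at day 25 stayed within their range over resampled genes, while 7 and 16 had the other sign. The hepatic-like class was not named at day 10 in 4 settings. At day 25 the definitive endoderm-like class was not named in 3, the endothelial-like class in 2 and the trophoblast-like class at Leiden resolution 0.25. The alternatives that leave out low-depth clusters or high doublet scores, keep called doublets, or cluster without hepatic or differing genes were chosen after seeing the data. Counting error is small at these depths, and the number of libraries limits the results.

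By construction of the floor, fewer or more genes were tested at other floors. At 5 CPM 246 genes were 2-fold apart at day 10 (164 higher, 82 lower) and 493 at day 25 (240 and 253), and at 100 CPM 19 (11 and 8) and 56 (33 and 23). The other differences named here have a cause that was not tested. The ribosomal protein median at day 10 turned to −0.046 under median-of-ratios scaling. The oxidative phosphorylation median at day 25 turned from −0.09 to 0.04 under that scaling, and the G2 and M phase median there was −0.64 with equal weight per cell and −0.44 without high doublet scores. The CDK5RAP3 ratio was −2.76 at day 10 with equal weight per cell, and at day 25 −2.75 under each of median-of-ratios scaling, totals without mitochondrial and ribosomal genes, and equal weight per cell. Class shares at day 25 are listed for all barcodes, the stricter filter, doublets kept, Leiden 1.0, Leiden 0.25, 30 neighbours, clustering without hepatic genes and clustering without differing genes. Mesenchymal-like control shares were 3.64%, 10.4%, 3.75%, 6.05%, 8.90%, 4.36%, 5.30% and 4.64% (3.02% as planned), and null shares 29.1%, 48.0%, 33.7%, 25.4%, 46.2%, 37.2%, 33.2% and 36.5% (27.7% as planned). Hepatic-like control shares were 57.7%, 47.4%, 15.5%, 15.4%, 59.4%, 11.4%, 59.6% and 54.1% (13.4% as planned). Hepatic-like null shares were 1.04% with all barcodes, 4.34% at Leiden 1.0, 23.5% at Leiden 0.25, 23.3% without hepatic genes and 21.1% without differing genes (0.683% as planned), and in the other 3 settings they lay within counting error of the planned share. The secreted protein median within hepatic-like cells at day 25, 0.02 as planned, was −1.35 at Leiden 1.0 and 0.26 under median-of-ratios scaling.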

Other observations

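The tests of X-linked genes, of BTF3 within clusters and of hepatic-like cells clustered without differing genes were chosen after the results were seen.

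Some genes differed the same way on both days. Of 5388 genes measured on both days, 9 were at least 2-fold higher in both null libraries (A1BG, AMMECR1, COL11A1, COL1A1, COL1A2, COL5A2, LINC00632, MT2A and TIMP1) and 6 at least 2-fold lower (BTF3, LRRC75A, PSAT1, TFF1, VTN and ZNF738), the members outside the naming rule being listed after their values were seen. Opposite directions were seen for 4 genes (DLK1, GAL, NTS and SPP1). Across genes, which are not independent replicates, the log2 ratios of the 2 days had a Pearson r of 0.278 and a Spearman rho of 0.260. BTF3 stood at 897 and 391 CPM in control and null at day 10 and at 1023 and 433 CPM at day 25. It was at least 2-fold lower in 11 of 11 planned clusters compared at day 10 and 10 of 12 at day 25. TIMP1 was at least 2-fold higher in 11 of 11 and 9 of 12. Some other members kept their direction, such as ZNF738 in 7 of 7 clusters on each day, and some did not. LRRC75A was at least 2-fold lower in 11 of 11 clusters at day 10 but below 0 in 2 of 9 at day 25 (median 0.51), and COL5A2 had medians within clusters of 0.18 at day 10 and 0.11 at day 25.

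S100A6, the gene with the highest ratio at day 25, was compared within classes after its value was seen. The gap was not limited to day 25. At day 10 S100A6 was higher in the null cells of each planned cluster with at least 20 cells in both libraries. In null and control cells it stood at 14.6 and 0.249 CPM in day 10 cluster 3 and at 54.8 and 0.0 CPM in day 10 cluster 10. Within day 25 hepatic-like cells outside low-depth clusters it stood at 334 CPM in null and 4.25 CPM in control cells. In a trophoblast-like planned cluster these levels were 1214 and 0.181 CPM, and in a pluripotent-like planned cluster 17.6 and 2.27 CPM. The same hepatic-like null cells had more RNA of AGR2, a secretory epithelial protein (log2 ratio 1.52), and of CDX2, an intestinal transcription factor (0.51), both chosen after their values were seen. Planned cluster 3, led by AGR2, held 96.6% of these null and 34.2% of these control cells, so the mix may account for a part. Within planned cluster 3, null and control cells stood at 306 and 194 CPM for AGR2 and 177 and 126 CPM for CDX2. Within planned cluster 5 the levels were 101 and 78.8 CPM for AGR2 and 90.0 and 95.7 CPM for CDX2. In the pooled hepatic-like class G2 and M phase genes stood at 0.85 (27 genes) and S phase genes at 0.32, opposite to the whole libraries. A cluster of this class with mitotic leading genes held 348 of its 1804 null cells and 94 of its 1361 control cells, so the mix of clusters may account for this.

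For the plasma protein genes low in the day 25 null library, the list median with equal weight per cell was −1.92. The low median thus did not rest on the larger UMI totals of deep cells. Whether a few deep control cells were the source of the RNA cannot be decided this way. Of the clustered control cells, 42.1% lay in a low-depth cluster that may hold a mixture of the library's RNA, and these count fully here. Among hepatic-like cells clustered without the differing genes the median was −1.74, but 60.6% of their control and 2.49% of their null cells lay in planned cluster 5, and medians within planned clusters 3 and 5 were −0.10 and −0.15. In the planned hepatic-like class, formed in part by these genes, it was 0.015, so fewer hepatic-like cells with equal levels cannot be told apart from lower levels. In the classes with other names pooled the list median was −0.28 (−0.82 to 0.19 over resampled genes). Medians were −0.66 to −0.83 in the mesenchymal-like, neural-like, pluripotent-like and trophoblast-like classes and 1.76 in the definitive endoderm-like class. Null cells of the last class had more APOA1 RNA (8267 CPM, and 1176 CPM in control). The size of a part from free RNA therefore cannot be told apart. ALB stood at 75.2 CPM in control cells of these classes. It was lower in the null cells of each of their clusters with at least 20 cells in both libraries. In pluripotent-like planned cluster 6, which should lack ALB, control and null cells stood at 66.2 and 4.86 CPM, a gap that free RNA would give. An effect of the knockout on hepatocyte maturation may contribute, but library, batch and line share every difference, and this stays untested.

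The day 25 control library held a low-depth cluster with 42.1% of its cells and 0.485% of null cells. Its leading genes included hepatic genes, and 32 markers of other classes had a median ratio of 1.01 to the rest of the library (0.700 to 1.22), against medians of 0.0962 to 0.746 in 9 named clusters. This is consistent with shallow droplets that carry a mixture of the library's RNA. An effect of the knockout on its leading genes cannot be told apart, since 3 of the 7 measured ones were also at least 2-fold lower in the null library in the other clusters. Clustered without differing genes, its counterpart held 6337 of the control cells called hepatic-like.

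For the genes 2-fold apart on both days, a different mix of cell classes was weighed. The median of the within-cluster ratio over the whole-library ratio was 0.676, so for the set as a whole class mix cannot be told apart from differences within cells. For BTF3 the highest ratio in any of 23 clusters was −0.92, which argues against class mix. Loss of 1 copy of its region is argued against by the other genes within 2 Mb, whose medians were 0.12 at day 10 (11 genes) and −0.20 at day 25 (12 genes). Of the 9 higher genes, 3 are X-linked, against 3.49% of measured genes, and X-linked medians lay at percentiles 98.6 and 100 (0.06 beside 0.03 for all genes at day 10, −0.05 beside −0.18 at day 25), so X-linked dosage may differ slightly between the lines.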
